A study of Mus musculus with 40 samples.

How the data were processed

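RNA of 8 B cell populations of female C57BL/6JNimr mice, 5 libraries per population, was read with a stranded poly(A) kit, per the labels' protocols. Pro, pre, immature and mature B cells came from bone marrow, follicular, marginal zone and germinal center B cells from spleen, and B1a cells from the peritoneal cavity. All were sorted by surface proteins. The mice were 7 to 9 weeks old, and those for germinal center cells 7 weeks old and immunised with sheep red blood cells. The deposited table holds raw counts of 26987 genes in the 40 libraries, without normalisation. Base calls were made with CASAVA 1.8.1, reads were aligned to mm10 with STAR 2.3.0e and counted with featureCounts of Subread 1.4.3, per the submitters' processing notes. The gene annotation, the strand setting and the handling of reads with several matches are not given in the sources used here, so counts of genes that overlap another gene, lie antisense to one or share reads with a close copy are uncertain. Of 242 printed genes with coordinates, 34 overlap another annotated gene of the table, 33 of these on the opposite strand.

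The table lists 22471 Ensembl identifiers and 4516 identifiers of the authors' own lncRNA catalogue, whose names and coordinates are not given in the sources used here. Of the Ensembl identifiers 21742 were matched to GENCODE M21 (GRCm38), which gave the symbol, class and coordinates, and 729 were not. This gave 20997 protein-coding genes and 4851 lncRNAs, of which 335 are Ensembl genes. The table holds few immunoglobulin and mitochondrial genes and 1 of 44 lncRNAs with known functions, so shares of the former and a test of the latter are left out.

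Genes were kept by the default filter of edgeR by population, which left 17117, 3822 of them lncRNAs. Libraries were scaled by TMM, and a quasi-likelihood negative binomial model with 1 coefficient per population was fitted to all 40 libraries (edgeR 4.0.16 with limma 3.58.1 in R 4.3.3). The biological coefficient of variation was 0.194. Each of 7 comparisons was a contrast of 5 against 5 libraries: pre with pro, immature with pre, mature with immature, follicular with mature, and marginal zone, germinal center and B1a with follicular. These 3 last comparisons share their follicular libraries. P-values were adjusted by the method of Benjamini and Hochberg, and a gene was called changed at an adjusted p below 0.05. The standard error of a log2 fold change is its absolute value over the square root of the F statistic. An F test over all populations and a search for genes at least 2-fold higher in 1 population than in each of the other 7, with every adjusted p below 0.05, used the same fit. LncRNAs were detected in a population at 1 CPM or more in all 5 of its libraries. Tau was computed from population means of log2(CPM + 1), with 10000 random sets of coding genes matched on the decile of the highest mean. Shares of counts were compared by a 2-sided exact permutation test, adjusted over 21 tests.

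Gene lists were written before the data were examined, as were the model, the comparisons and the alternatives, except where the text says that a test was chosen afterwards. Of 35 lists written, 31 had at least 5 tested members. They were tested with camera on log2 CPM (prior count 2) at its preset correlation between genes of 0.01, 2-sided, and adjusted over lists and comparisons together, 217 tests. Camera with an estimated correlation and fry, which asks whether a list moved at all, were run beside it. Named genes follow a rule: in each comparison, among called genes whose 5 CPM values in 1 population all lie above the 5 in the other, without immunoglobulin and T cell receptor segments and pseudogenes, they are taken from the 6 largest changes of each sign among coding genes with a mean of at least 10 CPM in the higher population. For lncRNAs it is the 4 largest of each sign with at least 1 CPM, of which at most 2 of each sign are printed. For each list past its test up to 4 called members with the largest change are taken, along with called members that moved against the list. Immunoglobulin constant genes, genes of the sorting gates and, for each population, the 3 coding genes and 3 lncRNAs with the largest smallest fold change over the other 7 complete the rule. It names 568 pairs of gene and comparison, of which the report prints 339. Which of them to print was decided after their values and their stability were seen, and some that changed sign or lost their call were left out, so those printed are the more stable part. For a gene without counts in 1 population the fold is a minimum against 3 counts over that population, and with 1 to 3 counts it is a ratio with a 95% counting interval.

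Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, robust dispersion shrinkage, no filter, a filter of 1 CPM in 5 libraries, only the 10 libraries of a comparison, no immunoglobulin genes, a replicate block, thinned counts and leaving out each library in turn. A covariate for the mean log2 CPM of neutrophil or macrophage genes was added after their levels were seen. Libraries with the same number were checked for shared deviations from their population means. Between pre and pro B cells all 5 pairs correlated (r from 0.21 to 0.49) and every library correlated best with its own number, so the numbers were taken to pair these libraries; the labels do not say what they mark. No 2 libraries were copies of each other (chi-square per degree of freedom of at least 4.56 between replicates).

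The calls were tested on data simulated for marginal zone with follicular cells (16817 genes). Of genes changed 1.5-, 2- and 4-fold, 70.1%, 92.5% and 92.4% were called, with 2 false calls (1.16% of calls). Of 50 genes raised 4-fold in a simulated population, 48 were found restricted, with 0 others. Rates may differ for weak lncRNAs and for mature libraries (chi-square up to 211.7).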

Results

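The libraries hold poly(A) RNA of 8 sorted mouse B cell populations, with 5 libraries each: pro, pre, immature and mature B cells of the bone marrow, follicular, marginal zone and germinal center B cells of the spleen, and B1a cells of the peritoneal cavity. Library totals ran from 16710164 counts (pro replicate 1) to 63299184 (mature replicate 3). Of 17117 tested genes, 16988 differed between at least 2 of the populations (99.2%, quasi-likelihood F test, adjusted p below 0.05), and for 13279 of them the highest and lowest population means lay at least 2-fold apart. Among 3822 tested lncRNAs the number was 3759. The first principal component held 41.5% of the variance and the second 18.3%. Germinal center replicate 14 scored -109.6 on the second component, where the other germinal center libraries scored from -167.8 to -155.1. Germinal center cells came from immunised mice, and the labels state no immunisation for the other populations, so any effect of immunisation is part of every germinal center difference. The labels do not say which libraries come from separate animals, so each p-value measures only the spread between these libraries.

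**Figure D1:**
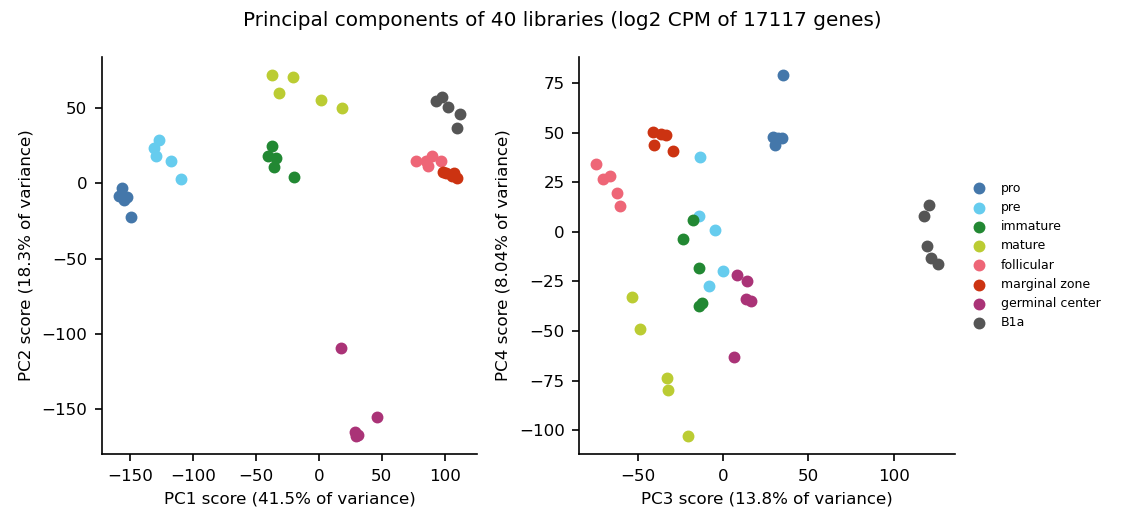
Scores of the 40 libraries (1 point each, coloured by population) on principal components 1 and 2 (left) and 3 and 4 (right) of log2 CPM; axis labels give the share of variance. On the left, germinal center libraries lie lowest.

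Of the 4851 lncRNAs in the table, 1923 reached 1 CPM (counts scaled to library size) in all 5 libraries of at least 1 population. Marginal zone cells held the most (1254), ahead of follicular cells (1092), and immature B cells the fewest (736). Only 364 lncRNAs (18.9%; 572 at 0.5 CPM) were detected in all 8 populations, against 9177 of 11750 protein-coding genes (78.1%). A single population held 557 lncRNAs (29%) and 720 coding genes (6.13%). The median of tau, an index of specificity that is 0 for an even gene and 1 for a gene of 1 population, was 0.553 for lncRNAs and 0.158 for coding genes. Coding genes matched to the lncRNAs on their highest population mean had a median tau of 0.603 (range of 10000 random sets 0.586 to 0.619), which lies above that of the lncRNAs. This is a description across genes, which are not replicates. LncRNAs made up 1.53% of counts in pro B cells and 2.11% in pre B cells (adjusted p = 0.0208, 2-sided exact permutation test, n = 5 against 5, for which 0.00794 is the smallest p possible before adjustment). These libraries were taken as paired, and exchange within the 5 pairs gave 0.0625, the smallest p possible there, so it cannot pass. The share was 2.50% in follicular cells, against 1.64% in germinal center cells (adjusted p = 0.0208) and 1.74% in mature B cells (adjusted p = 0.0455). The last did not pass without any 1 of 8 of the 10 libraries (adjusted p from 0.0606 to 0.106). Marginal zone (2.85%) and B1a cells (2.19%) did not differ from follicular cells on this test (adjusted p = 0.198 and 0.241), nor did immature from pre (adjusted p = 0.155) or mature from immature B cells (adjusted p = 0.849).

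**Figure D2:**
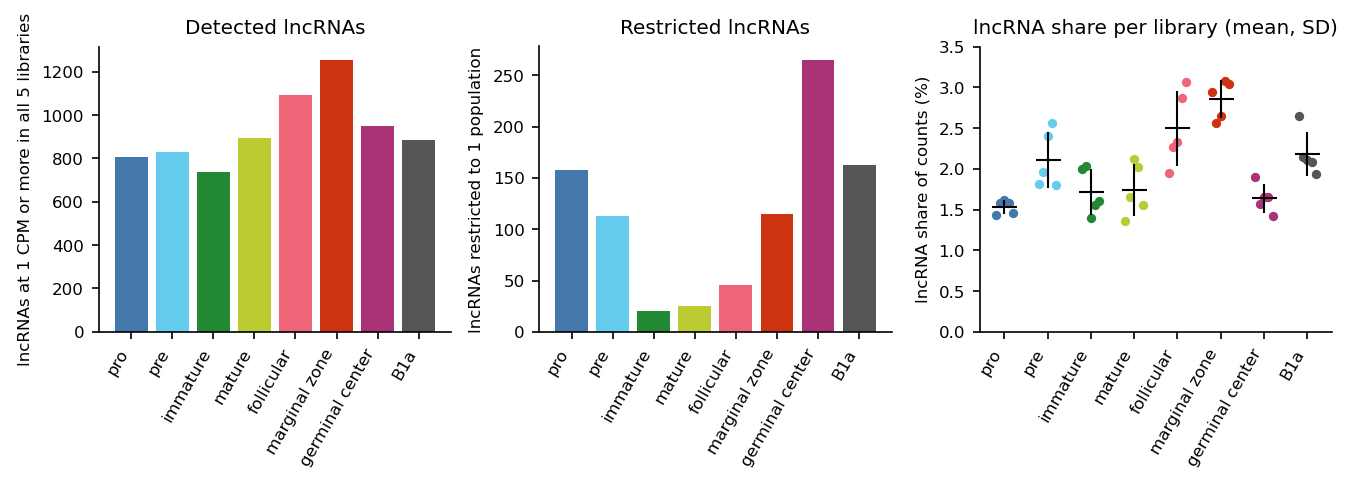
Number of lncRNAs detected in each population (left bars), number restricted to it (middle bars), and the lncRNA share of counts in percent (right; 1 point per library, black bars mean and SD, n = 5). Detection peaks at 1254 lncRNAs in marginal zone cells and restriction at 265 in germinal center cells.

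Transcripts typical of other blood cells were present in the bone marrow libraries. The 13 neutrophil genes of a fixed list, among them Mpo, Elane and Camp, took 1.51% of counts in mature B cells (SD 0.976, n = 5), 0.723% in pre, 0.297% in immature and 0.269% in pro B cells, and 0.00595% in follicular cells. Their share was higher in mature than in immature B cells (adjusted p = 0.0455) and lower in follicular than in mature cells (adjusted p = 0.0208, exact permutation test, n = 5 against 5). The first did not pass without any 1 of 8 of the 10 libraries (adjusted p from 0.05 to 0.125). Yet each mature library exceeded its same-numbered immature one. Macrophage genes took 0.237% in mature B cells and 0.162% in B1a cells, against 0.0130% in follicular cells (adjusted p = 0.0208 for each of the 2 comparisons). Both shares were lower in marginal zone than in follicular cells (adjusted p = 0.0208 for each), at 0.00123% and 0.00610% of counts.

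**Figure D3:**
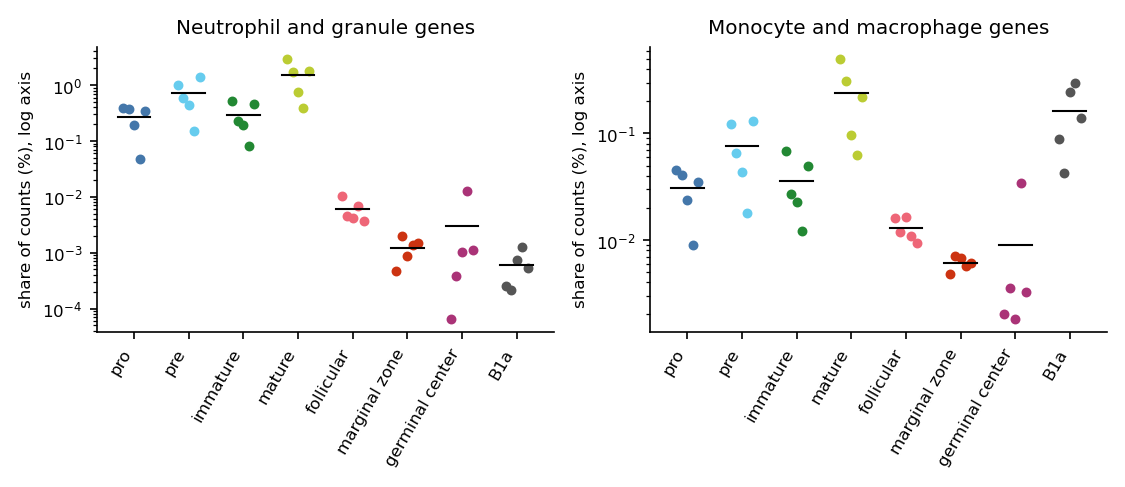
Share of counts in percent (log axis) from 13 neutrophil and granule genes (left) and 15 monocyte and macrophage genes (right); 1 point per library, black lines are means of 5. Mature B cell libraries lie highest on the left (mean 1.51%), mature and B1a libraries on the right (0.237% and 0.162%).

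In what follows, a value in parentheses after a gene is its log2 fold change ± standard error, from 5 libraries per population. "Did not pass" means an adjusted p of 0.05 or more. Members are those tested. In each of the 7 comparisons the direction that held more genes turned under some alternative. Upper-quartile scaling gave 5177 higher and 5292 lower for pre with pro, 4622 and 3957 for immature with pre, 4211 and 3982 for follicular with mature, 5375 and 6709 for germinal center and 4782 and 5972 for B1a cells. A filter of 1 CPM in 5 libraries gave 4013 and 4563 for mature with immature and 2168 and 2333 for marginal zone cells. Genes were named by a rule fixed before the data were examined, and those printed were picked after their values were seen.

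Pre B cells, which carry a rearranged immunoglobulin heavy chain, differed from pro B cells in 10574 genes (5741 higher and 4833 lower), 4219 of them by at least 2-fold. The largest rises were those of Reln (5.11 ± 0.25, adjusted p = 6.55e-19), a secreted glycoprotein gene, Ms4a1 (5.10 ± 0.16, adjusted p = 3.64e-24), which encodes CD20, Il2rb (5.0 ± 0.53), Col5a3 (5.0 ± 0.36), a collagen chain gene, and the phosphodiesterase gene Pde4c (4.62 ± 0.22). Largest among the falls were Dlx1 (-5.03 ± 0.39), a homeobox gene, Pde9a (-4.92 ± 0.37), Mmrn1 (-4.87 ± 0.41), Fxyd6 (-4.75 ± 0.36) and Dntt (-4.74 ± 0.29, adjusted p = 7.01e-16), which encodes the terminal transferase that adds nucleotides at V(D)J joints. Cd2 (4.40 ± 0.18), whose protein separated the 2 sorting gates, rose. The light chain constant gene Iglc2 (6.14 ± 0.24) rose as well, although reads cannot always be told apart between it and its close copies. Of lncRNAs, 1155 rose and 653 fell. LNCGmm02080 (7.49 ± 0.56) and LNCGme02078 (6.66 ± 0.49) rose most, and LNCGsm01566 (-5.59 ± 0.50) and LNCGse08164 (-5.53 ± 0.43) fell most.

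All 15 MHC class II presentation genes rose, the same adjusted over the list alone (camera adjusted p = 3.04e-06, adjusted p = 0.433 with an estimated correlation). Cd40 (3.64 ± 0.14), a receptor for T cell help, H2-DMb2 (3.43 ± 0.17) and the invariant chain gene Cd74 (2.38 ± 0.23) were among them. In the B cell receptor signalling list 22 of 28 members rose, 3 fell and 3 did not pass, the same adjusted over the list alone (camera adjusted p = 6.26e-06, adjusted p = 0.442 with an estimated correlation). The kinase gene Syk (1.65 ± 0.11), Siglecg (1.49 ± 0.14) and Cd79b (1.48 ± 0.12) rose there, while Fyn (-0.80 ± 0.08) and Cd81 (-0.56 ± 0.08) fell. Survival genes of the TNF receptor and NF-kB families moved the same way, as 12 of 19 members rose, 3 fell and 4 did not pass, the same adjusted over the list alone (camera adjusted p = 0.00124, adjusted p = 0.216 with an estimated correlation). Examples were Relb (2.26 ± 0.13) and Nfkb2 (2.07 ± 0.14), with Tnfrsf8 (-3.74 ± 0.50) as the largest fall. Immediate early genes counted 19 of 28 that rose and 2 that fell (19 and 2 adjusted over the list alone; camera adjusted p = 2.12e-04, adjusted p = 0.540 with an estimated correlation); Cd83 (4.22 ± 0.28) rose and Myc (-2.25 ± 0.21) fell. For B cell transcription factors 13 of 22 members rose, 4 fell and 5 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0308, adjusted p = 0.731 with an estimated correlation). Spib (1.98 ± 0.13) and Ikzf3 (1.88 ± 0.13) rose, and Mef2c (-0.65 ± 0.10) and Etv6 (-0.63 ± 0.13) fell. All 29 DNA replication genes fell, the same adjusted over the list alone (camera adjusted p = 3.22e-12, adjusted p = 0.524 with an estimated correlation). Chaf1b (-1.93 ± 0.19), Gins2 (-1.83 ± 0.22) and the helicase subunit gene Mcm6 (-1.67 ± 0.17) were the clearest. Of mitosis genes, 9 of 29 members fell, 0 rose and 20 did not pass, and 0 fell and 0 rose adjusted over the list alone (camera adjusted p = 0.0392, adjusted p = 0.819 with an estimated correlation). Bub1b (-0.73 ± 0.23) led these falls.

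Migration and homing receptors included Cnr2 (4.25 ± 0.13), a cannabinoid receptor gene, and Gpr183 (3.38 ± 0.24) among the rises and Ccr9 (-1.88 ± 0.52) and Itga4 (-0.57 ± 0.14) among the falls. Here 14 of 25 members rose, 4 fell and 7 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0114, adjusted p = 0.731 with an estimated correlation). In the glycolysis list 14 of 20 members fell, 2 rose and 4 did not pass, and 14 fell and 3 rose adjusted over the list alone (camera adjusted p = 0.00329, adjusted p = 0.771 with an estimated correlation). The kinase gene Pdk1 (-1.64 ± 0.10) and Ldha (-1.46 ± 0.17) fell there, and Slc16a3 (1.36 ± 0.48) rose, but not with the granule gene level in the model (adjusted p = 0.244) or in only these 10 libraries (0.0612). Cholesterol synthesis genes such as Sqle (-1.76 ± 0.19) and Dhcr24 (-1.76 ± 0.15) fell, against a rise of Hsd17b7 (0.56 ± 0.11). In all 13 of 21 members fell, 3 rose and 5 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0104, adjusted p = 0.771 with an estimated correlation). DNA repair genes of somatic hypermutation counted 12 of 17 that fell and 3 that rose (13 and 3 adjusted over the list alone; camera adjusted p = 0.00277, adjusted p = 0.338 with an estimated correlation), with Ung (-2.26 ± 0.19) and Exo1 (-1.61 ± 0.19) lower and Smug1 (0.90 ± 0.09) higher. Plasma cell genes were led by Prdm1 (2.78 ± 0.40), a repressor of the B cell state, and Derl3 (2.21 ± 0.29), with Mzb1 (-0.58 ± 0.17) lower. In all 10 of 19 members rose, 1 fell and 8 did not pass, and 11 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0409, adjusted p = 0.819 with an estimated correlation). With a replicate block that list did not pass (adjusted p = 0.0648), nor with the granule (0.0967) or macrophage gene level (0.0673). Block values of the next lists are not given here. Genes of other cells rose as well, though their lists did not pass: 11 of 13 neutrophil genes (13 adjusted over the list alone, camera adjusted p = 0.328), 10 of 11 erythroid (10, 0.198), 7 of 8 mast cell and basophil (7, 0.266) and 6 of 9 natural killer genes (6, 0.136), with 1 of the last lower. Of the fixed lists, 13 of 31 passed, 8 higher and 5 lower; their adjusted p ran from 0.216 to 0.819 with an estimated correlation.

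Immature B cells, the first to carry surface IgM, differed from pre B cells in 8663 genes (4146 higher and 4517 lower), 3634 of them by at least 2-fold. Both recombinase genes fell, Rag1 (-5.86 ± 0.29, adjusted p = 6.11e-19) and Rag2 (-5.71 ± 0.27, adjusted p = 2.54e-18). Lrrc10b (-5.76 ± 0.38), the G protein regulator gene Rgs16 (-5.30 ± 0.37), the calcium channel subunit gene Cacna2d1 (-4.90 ± 0.32) and Smtnl2 (-4.90 ± 0.25) fell as strongly. The largest rises were Shisa8 (5.43 ± 0.33, adjusted p = 2.04e-16), AF067061 (5.28 ± 0.40), the complement receptor gene Cr2 (4.91 ± 0.22), the cation channel gene Trpm5 (4.57 ± 0.27) and Fcrl5 (4.55 ± 0.29). Among gate genes Fcer2a (4.47 ± 0.27), which encodes CD23, rose, Cd93 (-2.04 ± 0.26), which encodes AA4.1, fell, and Cd2 (-0.07 ± 0.15) did not pass (adjusted p = 0.720). LncRNAs rose in 824 cases and fell in 838. LNCGme01995 (5.84 ± 0.35) and LNCGse08407 (5.25 ± 0.35) were among the largest rises, LNCGme01891 (-6.54 ± 0.53) and LNCGme00468 (-6.52 ± 0.54) the largest falls.

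The rise of MHC class II genes went on, with H2-DMb2 (3.71 ± 0.16), Cd74 (3.65 ± 0.24) and H2-Eb1 (3.12 ± 0.26). All 15 members rose, the same adjusted over the list alone (camera adjusted p = 8.08e-16, adjusted p = 0.0980 with an estimated correlation). Survival genes gave the list that also passed with an estimated correlation, as 15 of 19 members rose, 0 fell and 4 did not pass, the same adjusted over the list alone (camera adjusted p = 1.93e-07, adjusted p = 0.0303 with an estimated correlation). Lta (4.46 ± 0.22), Ltb (3.17 ± 0.22) and Tnfrsf13c (2.38 ± 0.12), which encodes the BAFF receptor, rose there. In the interferon response list 20 of 26 members rose, 0 fell and 6 did not pass, and 21 rose and 0 fell adjusted over the list alone (camera adjusted p = 6.80e-07, adjusted p = 0.524 with an estimated correlation). Mx1 (2.20 ± 0.24), Oasl1 (1.48 ± 0.13) and Zbp1 (1.46 ± 0.11) were highest. B cell receptor signalling genes moved upward, led by Card11 (3.20 ± 0.14), Cd22 (2.35 ± 0.12) and the phosphatase gene Ptpn6 (2.33 ± 0.10), with Blnk (-0.59 ± 0.11) lower. In all 18 of 28 members rose, 4 fell and 6 did not pass, and 19 rose and 4 fell adjusted over the list alone (camera adjusted p = 1.90e-06, adjusted p = 0.427 with an estimated correlation). Genes of the B1 programme followed, as 15 of 21 members rose, 3 fell and 3 did not pass, the same adjusted over the list alone (camera adjusted p = 1.45e-06, adjusted p = 0.232 with an estimated correlation). Bhlhe40 (3.99 ± 0.23), Zbtb32 (3.55 ± 0.27) and Il5ra (3.0 ± 0.14) rose, and Spn (-1.25 ± 0.21), which encodes CD43, fell. The marginal zone list gave Cd36 (3.08 ± 0.21) and Hes5 (2.69 ± 0.23) as rises and Asb2 (-2.26 ± 0.45) and Ebf1 (-1.21 ± 0.11) as falls. In all 10 of 18 members rose, 4 fell and 4 did not pass, and 10 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.00724, adjusted p = 0.442 with an estimated correlation). Germinal center genes counted 11 of 19 that rose and 4 that fell (11 and 4 adjusted over the list alone; camera adjusted p = 0.0392, adjusted p = 0.524 with an estimated correlation). This call was lost in only these 10 libraries (adjusted p = 0.0638) and without immature replicate 1 (0.0642). The cytidine deaminase gene Aicda (3.20 ± 0.22) and Lmo2 (2.33 ± 0.22) rose there, while Ezh2 (-2.31 ± 0.13) and Neil1 (-2.01 ± 0.12) fell.

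Mitosis genes fell throughout, among them the cyclin genes Ccnb1 (-2.68 ± 0.32) and Ccnb2 (-2.33 ± 0.27) and the kinase gene Cdk1 (-2.20 ± 0.31). All 29 members fell, the same adjusted over the list alone (camera adjusted p = 2.22e-12, adjusted p = 0.524 with an estimated correlation). For DNA replication 18 of 29 members fell, 1 rose and 10 did not pass, and 20 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.00355, adjusted p = 0.819 with an estimated correlation). Rrm2 (-1.58 ± 0.25) fell most and Cdt1 (0.36 ± 0.13) rose, but not in only these 10 libraries (adjusted p = 0.0754). The early B progenitor list was lower, as 15 of 17 members fell, 1 rose and 1 did not pass, the same adjusted over the list alone (camera adjusted p = 3.65e-06, adjusted p = 0.216 with an estimated correlation). Il7r (-4.88 ± 0.46), the receptor gene for interleukin 7, and the surrogate light chain genes Igll1 (-3.44 ± 0.36) and Vpreb1 (-3.19 ± 0.28) fell, and Crlf2 (0.58 ± 0.13) rose. V(D)J recombination genes other than Rag1 and Rag2 included Xrcc6 (-3.05 ± 0.12) as a fall and Poll (1.29 ± 0.14) as a rise. Here 8 of 12 members fell, 3 rose and 1 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0312, 0.0509 with a replicate block, 0.244 with an estimated correlation). Of migration receptors, 13 of 25 members rose, 2 fell and 10 did not pass, the same adjusted over the list alone (camera adjusted p = 0.00210, adjusted p = 0.545 with an estimated correlation). Cxcr5 (4.29 ± 0.22), which guides cells to follicles, rose and Cxcr4 (-1.89 ± 0.21), which holds cells in the marrow, fell. Immediate early genes split. In all 12 of 28 members rose, 7 fell and 9 did not pass, and 12 rose and 8 fell adjusted over the list alone (camera adjusted p = 0.0262, adjusted p = 0.771 with an estimated correlation). The list did not pass in only these 10 libraries (adjusted p = 0.176), with a replicate block (0.0536) or without pre replicate 1 (0.0512) or immature replicate 3 (0.0541). Egr1 (2.70 ± 0.19) and Egr2 (2.59 ± 0.21) rose while Cd69 (-1.05 ± 0.16) and Btg2 (-0.94 ± 0.12) fell. Among the fixed lists, 13 of 31 passed, 9 higher and 4 lower; their adjusted p ran from 0.0303 to 0.819 with an estimated correlation.

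Mature B cells of the marrow differed from immature B cells in 9565 genes (4804 higher and 4761 lower), 4037 of them by at least 2-fold. Mapk12 (4.76 ± 0.23, adjusted p = 2.51e-18), Rapgef4 (4.57 ± 0.20, adjusted p = 2.15e-19), the chemokine receptor gene Ccr6 (4.49 ± 0.28), the receptor gene Il9r (4.45 ± 0.27) and Pglyrp2 (4.40 ± 0.33) rose most among genes outside the lists of other cells. The falls were led by Agbl1 (-4.31 ± 0.30), the signalling ligand genes Wnt10a (-4.31 ± 0.29) and Wnt10b (-4.23 ± 0.24), Aicda (-4.30 ± 0.24, adjusted p = 1.44e-16) and Map2 (-4.28 ± 0.23). Fcer2a (2.02 ± 0.24) rose and Cd93 (-1.48 ± 0.26) fell, while Cd2 (0.15 ± 0.15) did not pass (adjusted p = 0.400). Of lncRNAs, 1190 rose and 622 fell. LNCGme01582 (7.18 ± 0.47) and LNCGme02063 (6.37 ± 0.43) were among the largest rises, LNCGme00184 (-5.15 ± 0.47) and LNCGme02251 (-4.99 ± 0.54) the largest falls.

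Migration and homing genes rose, with Sell (3.22 ± 0.32), which encodes L-selectin, and Gpr183 (3.14 ± 0.17) highest and S1pr3 (-3.13 ± 0.18) as the only fall. Here 14 of 25 members rose, 1 fell and 10 did not pass, the same adjusted over the list alone (camera adjusted p = 0.00210, adjusted p = 0.545 with an estimated correlation). For MHC class II presentation 12 of 15 members rose, 1 fell and 2 did not pass, the same adjusted over the list alone (camera adjusted p = 1.31e-06, adjusted p = 0.420 with an estimated correlation). Icosl (3.21 ± 0.23), H2-Aa (2.74 ± 0.22) and the transactivator gene Ciita (2.0 ± 0.11) rose, while Cd40 (-0.92 ± 0.12) fell. B cell receptor signalling genes leaned lower, as 15 of 28 members fell, 6 rose and 7 did not pass, and 15 fell and 7 rose adjusted over the list alone (camera adjusted p = 0.0479, adjusted p = 0.819 with an estimated correlation). Cd72 (-2.15 ± 0.12) and Siglecg (-1.18 ± 0.14) fell there, against rises of Cr2 (1.90 ± 0.19), Rasgrp3 (1.33 ± 0.13) and Fyn (0.78 ± 0.08). The list did not pass with RLE scaling (adjusted p = 0.0575), a replicate block (0.0609) or only these 10 libraries (0.156). Nor did it with the granule (0.283) or macrophage gene level (0.501) in the model, or without any 1 of 5 libraries (0.0512 to 0.106). Among plasma cell genes Derl3 (-2.47 ± 0.29) and Edem1 (-1.30 ± 0.09), which act in disposal of misfolded protein, were lower. In all 15 of 19 members fell, 0 rose and 4 did not pass, the same adjusted over the list alone (camera adjusted p = 0.00102, adjusted p = 0.731 with an estimated correlation). Somatic hypermutation genes besides Aicda that fell were Ung (-1.17 ± 0.19), Apex1 (-1.14 ± 0.13) and Rev1 (-1.01 ± 0.07). In all 11 of 17 members fell, 0 rose and 6 did not pass, the same adjusted over the list alone (camera adjusted p = 4.84e-04, adjusted p = 0.216 with an estimated correlation). In the chromatin silencing list 11 of 18 members fell, 3 rose and 4 did not pass, and 13 fell and 3 rose adjusted over the list alone (camera adjusted p = 0.0164, adjusted p = 0.216 with an estimated correlation). The Polycomb genes Cbx2 (-1.61 ± 0.14) and Cbx8 (-1.22 ± 0.10) fell, and Cbx7 (1.01 ± 0.13) and Ezh1 (0.50 ± 0.08) rose. DNA replication genes such as E2f1 (-1.23 ± 0.16) and Rfc3 (-0.97 ± 0.10) were lower. Here 15 of 29 members fell, 0 rose and 14 did not pass, the same adjusted over the list alone (camera adjusted p = 0.00153, adjusted p = 0.819 with an estimated correlation).

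Lists of other cells rose in the same libraries. All 13 neutrophil genes rose, the same adjusted over the list alone (camera adjusted p = 0.0208, adjusted p = 0.819 with an estimated correlation). For macrophage genes 14 of 15 members rose, 0 fell and 1 did not pass, the same adjusted over the list alone (camera adjusted p = 3.57e-04, adjusted p = 0.765 with an estimated correlation). Fcgr1 (4.36 ± 0.72), an Fc receptor gene, and the complement genes C1qb (3.90 ± 0.67) and C1qa (3.76 ± 0.66) were highest. Mast cell and basophil genes included Fcer1a (4.46 ± 0.66) and Ms4a2 (4.04 ± 0.50). In all 7 of 8 members rose, 0 fell and 1 did not pass, the same adjusted over the list alone (camera adjusted p = 0.00149, adjusted p = 0.545 with an estimated correlation). Dendritic cell genes included Cd209a (4.30 ± 0.80) and Clec10a (3.83 ± 0.72). In all 8 of 10 members rose, 0 fell and 2 did not pass, the same adjusted over the list alone (camera adjusted p = 0.00829, adjusted p = 0.765 with an estimated correlation). The list of natural killer cells counted 8 of 9 that rose and 0 that fell (8 and 0 adjusted over the list alone; camera adjusted p = 0.0312, adjusted p = 0.805 with an estimated correlation), among them Nkg7 (2.72 ± 0.66) and Gzma (2.03 ± 0.64). Of the fixed lists, 12 of 31 passed, 7 higher and 5 lower; their adjusted p ran from 0.216 to 0.819 with an estimated correlation.

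Follicular B cells of the spleen differed from mature B cells of the marrow in 7788 genes (3346 higher and 4442 lower), 3626 of them by at least 2-fold. The rises were modest: S1pr3 (2.19 ± 0.18, adjusted p = 4.06e-12), the phosphatase gene Dusp4 (2.03 ± 0.20, adjusted p = 4.89e-10), Cr2 (1.76 ± 0.19), the early response gene Egr3 (1.61 ± 0.16), the cytokine gene Tnf (1.51 ± 0.23) and Fam167a (1.4 ± 0.15). Among the largest falls were genes of granulocyte precursors, Elane (-10.22 ± 0.92), Ms4a3 (-9.74 ± 0.93), Prtn3 (-9.48 ± 0.91) and Mpo (-9.44 ± 0.81). Cd38 (0.70 ± 0.15) and Fcer2a (0.72 ± 0.23) rose and Cd93 (-1.46 ± 0.26) fell. LncRNAs rose in 1409 cases and fell in 415. LNCGmm01770 (3.21 ± 0.35) and LNCGsm09194 (3.07 ± 0.33) rose most, and LNCGme00082 (-8.78 ± 0.86) and LNCGme00002 (-8.39 ± 0.86) were among the largest falls. Tissue differs along with cell type here, and with each library's granule gene level in the model 1690 genes passed in place of 7788.

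Mitosis genes fell throughout, Ube2c (-5.70 ± 0.43), Ccna2 (-5.44 ± 0.37) and Birc5 (-5.22 ± 0.35) most. All 29 members fell, the same adjusted over the list alone (camera adjusted p = 1.99e-32, adjusted p = 0.177 with an estimated correlation). DNA replication genes followed, with Ccne2 (-4.67 ± 0.36), Mcm10 (-4.37 ± 0.34) and Cdc6 (-4.19 ± 0.34). In all 28 of 29 members fell, 0 rose and 1 did not pass, and 29 fell and 0 rose adjusted over the list alone (camera adjusted p = 5.40e-15, adjusted p = 0.442 with an estimated correlation). In the early B progenitor list 14 of 17 members fell, 0 rose and 3 did not pass, the same adjusted over the list alone (camera adjusted p = 7.54e-08, adjusted p = 0.163 with an estimated correlation). The transcription factor gene Erg (-6.63 ± 0.44) fell, and Igll1 was 826-fold (95% counting interval 228 to 6830) lower in follicular cells. Glycolysis genes such as Slc16a1 (-1.26 ± 0.17) and Pfkm (-1.26 ± 0.24) were lower. In all 15 of 20 members fell, 0 rose and 5 did not pass, and 16 fell and 0 rose adjusted over the list alone (camera adjusted p = 0.00352, adjusted p = 0.771 with an estimated correlation). With the granule gene level in the model this list leaned higher without passing (adjusted p = 0.110), and with the macrophage gene level it did not pass (adjusted p = 0.0552). Cholesterol synthesis genes rose, with Cyp51 (1.01 ± 0.13), Idi1 (1.02 ± 0.17) and Hmgcs1 (0.79 ± 0.10). Here 13 of 21 members rose, 0 fell and 8 did not pass, the same adjusted over the list alone (camera adjusted p = 2.96e-05, adjusted p = 0.524 with an estimated correlation). For B cell receptor signalling 10 of 28 members rose, 1 fell and 17 did not pass, the same adjusted over the list alone (camera adjusted p = 0.00882, adjusted p = 0.771 with an estimated correlation). Rasgrp3 (0.66 ± 0.13), Cd72 (0.62 ± 0.12) and Cd22 (0.54 ± 0.12) rose. With the granule gene level in the model this list was lower (camera adjusted p = 0.0415).

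Every other-cell list that passed was lower. All 13 neutrophil genes fell, the same adjusted over the list alone (camera adjusted p = 6.19e-13, adjusted p = 0.232 with an estimated correlation). Ctsg (-9.44 ± 0.88) was among them. Erythroid genes included Slc4a1 (-5.94 ± 0.84) and Epor (-4.66 ± 0.71). All 11 members fell, the same adjusted over the list alone (camera adjusted p = 1.27e-06, adjusted p = 0.512 with an estimated correlation). Mast cell and basophil genes Prss34 (-9.40 ± 0.74) and Mcpt8 (-9.28 ± 0.81) fell. In all 6 of 8 members fell, 0 rose and 2 did not pass, the same adjusted over the list alone (camera adjusted p = 7.78e-06, adjusted p = 0.338 with an estimated correlation). For the macrophage list 12 of 15 members fell, 0 rose and 3 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0340, adjusted p = 0.819 with an estimated correlation). With the granule gene level in the model this list was higher (adjusted p = 3.78e-07), and without any 1 of 3 libraries it did not pass (0.0608 to 0.144). All 6 platelet genes fell (6 adjusted over the list alone, camera adjusted p = 0.00210, adjusted p = 0.545 with an estimated correlation), among them Pf4 (-5.74 ± 0.84) and Itga2b (-3.35 ± 0.35). The mesothelial and stromal list counted 6 of 6 that fell (6 adjusted over the list alone; camera adjusted p = 0.00220, adjusted p = 0.216 with an estimated correlation), among them the collagen gene Col1a1 (-7.33 ± 1.07) and the chemokine gene Cxcl12 (-4.62 ± 0.50). Among the fixed lists, 12 of 31 passed, 2 higher and 10 lower; their adjusted p ran from 0.163 to 0.819 with an estimated correlation.

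Marginal zone B cells differed from follicular B cells in 4550 genes (2607 higher and 1943 lower), 1799 of them by at least 2-fold. The metalloprotease gene Adam28 was 2080-fold (95% counting interval 373 to 82300) higher. Tsga13 (7.76 ± 0.43, adjusted p = 3.42e-13), Tmod2 (6.06 ± 0.47), Tspan15 (5.83 ± 0.57) and the chemokine scavenger gene Ackr2 (5.79 ± 0.22) rose as well. The falls were smaller and led by the calcium channel gene Ryr2 (-3.77 ± 0.38, adjusted p = 7.04e-10), Dusp4 (-3.38 ± 0.22, adjusted p = 7.67e-15), Ndrg1 (-3.27 ± 0.19), Rgl1 (-3.22 ± 0.24), Car2 (-3.04 ± 0.47) and Sdc1 (-2.92 ± 0.32), which encodes CD138. Fcer2a (-1.81 ± 0.23), whose protein was gated low in marginal zone cells, and Ptprc (-0.35 ± 0.09) fell, and Cd2 (-0.22 ± 0.15) did not pass (adjusted p = 0.301, but 0.0262 in only these 10 libraries). Of lncRNAs, 736 rose and 345 fell. LNCGsm05311 was at least 68-fold higher and LNCGmm02390 (7.90 ± 0.48) rose, and LNCGme02063 (-3.38 ± 0.33) and LNCGse04329 (-3.33 ± 0.32) fell most. Folds given as a minimum compare with a floor of 3 counts over a population without counts, and they and the counting intervals cover counting error only.

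The marginal zone list passed both ways, as 12 of 18 members rose, 2 fell and 4 did not pass, and 13 rose and 2 fell adjusted over the list alone (camera adjusted p = 1.28e-11, adjusted p = 0.0180 with an estimated correlation). S1pr3 (4.31 ± 0.18), Myof (4.18 ± 0.28) and Asb2 (3.90 ± 0.46) rose. Genes of the B1 programme were higher, among them Zbtb32 (4.61 ± 0.26), Cd9 (3.67 ± 0.32), Fcrl5 (3.33 ± 0.24) and the cytokine gene Il10 (3.81 ± 0.53). Here 15 of 21 members rose, 0 fell and 6 did not pass, and 15 rose and 1 fell adjusted over the list alone (camera adjusted p = 6.98e-10, adjusted p = 0.160 with an estimated correlation). For mitosis 15 of 29 members rose, 1 fell and 13 did not pass, and 17 rose and 1 fell adjusted over the list alone (camera adjusted p = 9.86e-06, adjusted p = 0.771 with an estimated correlation). Cenpf (1.95 ± 0.43), Nek2 (1.91 ± 0.29) and Mki67 (1.90 ± 0.30) rose, and Cdc25b (-0.58 ± 0.09) fell. Immediate early genes leaned lower, with Cd83 (-1.22 ± 0.18), Egr3 (-1.16 ± 0.15) and Ier2 (-1.08 ± 0.21) against a rise of Myc (1.01 ± 0.21). In all 9 of 28 members fell, 1 rose and 18 did not pass, the same adjusted over the list alone (camera adjusted p = 0.00182, adjusted p = 0.717 with an estimated correlation). In the cholesterol synthesis list 8 of 21 members fell, 1 rose and 12 did not pass, and 11 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0126, adjusted p = 0.771 with an estimated correlation). The regulator gene Srebf2 (-0.43 ± 0.10) fell by less than 2-fold. Of neutrophil genes, 7 of 13 members fell, 0 rose and 6 did not pass, the same adjusted over the list alone (camera adjusted p = 8.53e-04, adjusted p = 0.765 with an estimated correlation). Ngp (-2.94 ± 0.81) and Ltf (-2.83 ± 0.80) were lower in marginal zone cells, but neither passed with limma-voom (adjusted p = 0.0665 and 0.0820). The erythroid list counted 2 of 11 that fell, of which Car2 is given above, and 9 that did not pass (2 fell adjusted over the list alone; camera adjusted p = 0.0162, adjusted p = 0.805 with an estimated correlation). Of the fixed lists, 7 of 31 passed, 3 higher and 4 lower; their adjusted p ran from 0.0180 to 0.805 with an estimated correlation.

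Germinal center B cells differed from follicular B cells in 12047 genes (6231 higher and 5816 lower), 6353 of them by at least 2-fold. Aicda (11.68 ± 0.31, adjusted p = 7.16e-27), the deaminase gene of hypermutation and class switching, H1fx (11.25 ± 0.47, adjusted p = 1.93e-21) and Gcsam (10.12 ± 0.60) rose most among genes with more than 3 follicular counts. The chemokine scavenger gene Ackr4 was 9760-fold (95% counting interval 1750 to 386000) higher and Dnase1 1140-fold (95% counting interval 316 to 9450). Largest among the falls were Crip3 (-8.09 ± 0.54), Kctd14 (-5.70 ± 0.29), Gad1 (-5.64 ± 0.35), Maml3 (-5.63 ± 0.34) and Cnn3 (-5.61 ± 0.26). Genes of the sorting gate moved with it: Fas (4.76 ± 0.25) rose and Cd38 (-3.18 ± 0.16) fell. The heavy chain gene Ighe was 1790-fold (95% counting interval 320 to 70700) higher and Ighg2c (4.43 ± 0.86) rose, while Iglc2 (-1.39 ± 0.19) fell. LncRNAs fell in 1694 cases and rose in 949. LNCGse07016 was at least 720-fold and LNCGme01702 at least 413-fold higher, and LNCGme00160 (-6.91 ± 0.40) and LNCGme00785 (-6.75 ± 0.56) fell most. The median log2 fold change was -0.51 for lncRNAs and 0.07 for coding genes. Germinal center replicate 14 held 0.0342% of counts from macrophage genes, against 0.00182% to 0.00358% in the other 4, and without it 12473 genes passed.

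All 29 mitosis genes rose, the same adjusted over the list alone (camera adjusted p = 4.36e-17, adjusted p = 0.420 with an estimated correlation). Mki67 (7.20 ± 0.37), Birc5 (7.04 ± 0.36) and Ccna2 (6.83 ± 0.39) were highest. All 29 DNA replication genes rose, the same adjusted over the list alone (camera adjusted p = 6.32e-16, adjusted p = 0.427 with an estimated correlation). Mcm10 (6.82 ± 0.35), Ccne2 (6.73 ± 0.37) and Cdc6 (6.52 ± 0.36) led. In the germinal center list 16 of 19 members rose, 2 fell and 1 did not pass, the same adjusted over the list alone (camera adjusted p = 1.08e-06, adjusted p = 0.0303 with an estimated correlation). The sphingosine phosphate receptor gene S1pr2 (8.42 ± 0.45) and Nuggc (8.24 ± 0.40) rose, and Lmo2 (-1.45 ± 0.21) fell besides Cd38. Hypermutation genes Exo1 (3.87 ± 0.21), Ung (3.0 ± 0.20) and the polymerase gene Polh (2.75 ± 0.13) rose, with Smug1 (-1.02 ± 0.09) and Trp53bp1 (-0.53 ± 0.09) lower. In all 13 of 17 members rose, 2 fell and 2 did not pass, and 14 rose and 2 fell adjusted over the list alone (camera adjusted p = 1.81e-04, adjusted p = 0.216 with an estimated correlation). Cholesterol synthesis genes such as Dhcr24 (2.32 ± 0.15), Fdps (2.14 ± 0.17) and Sqle (1.91 ± 0.19) were higher. Here 19 of 21 members rose, 0 fell and 2 did not pass, the same adjusted over the list alone (camera adjusted p = 2.06e-06, adjusted p = 0.442 with an estimated correlation). For the interferon response 22 of 26 members fell, 1 rose and 3 did not pass, the same adjusted over the list alone (camera adjusted p = 1.08e-06, adjusted p = 0.524 with an estimated correlation). Oas2 (-3.82 ± 0.28), Mx1 (-3.26 ± 0.27) and Ddx58 (-2.98 ± 0.13), which encodes the RNA sensor RIG-I, fell, and Isg20 (0.82 ± 0.22) rose. Homing genes leaned lower, with Sell (-5.41 ± 0.36), Ccr7 (-4.67 ± 0.30) and Ccr6 (-4.59 ± 0.27) against rises of S1pr3 (2.93 ± 0.17) and Itgb1 (1.89 ± 0.18). In all 14 of 25 members fell, 8 rose and 3 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0317, adjusted p = 0.771 with an estimated correlation). It did not pass in only these 10 libraries (adjusted p = 0.102) or with the granule (0.0790) or macrophage gene level (0.0714) in the model. Immediate early genes counted 16 of 28 that fell and 6 that rose (16 and 7 adjusted over the list alone; camera adjusted p = 0.0403, adjusted p = 0.805 with an estimated correlation); Klf4 (-3.17 ± 0.30) and Jun (-2.62 ± 0.46) fell and Atf3 (2.74 ± 0.46) rose. Among the fixed lists, 8 of 31 passed, 5 higher and 3 lower; their adjusted p ran from 0.0303 to 0.805 with an estimated correlation.

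B1a cells of the peritoneal cavity differed from follicular B cells of the spleen in 10518 genes (5344 higher and 5174 lower), 5160 of them by at least 2-fold, and the site of the cells differs along with their type. The keratin gene Krt8 was at least 3730-fold higher, with no follicular counts. Ahnak2 (12.86 ± 0.31, adjusted p = 1.28e-28) rose, the G protein subunit gene Gnb3 was 7100-fold (95% counting interval 1270 to 280000) higher, and the synapsin gene Syn3 at least 626-fold. Vcam1, an adhesion gene, was 1090-fold (95% counting interval 301 to 8990) lower; Emid1 (-9.08 ± 0.29, adjusted p = 6.82e-25), Dusp4 (-7.53 ± 0.30), the iron exporter gene Slc40a1 (-7.54 ± 1.0) and Rflnb (-7.41 ± 0.56) fell. Of gate genes, Cd5 (3.27 ± 0.32) rose and Fcer2a (-8.44 ± 0.32) and Ptprc (-1.08 ± 0.09) fell, as their proteins were gated. LncRNAs fell in 1588 cases and rose in 671. LNCGme02460 was 2780-fold (95% counting interval 951 to 13500) and LNCGse11843 at least 323-fold higher, LNCGmm01922 at least 598-fold and LNCGme00443 at least 316-fold lower. The median log2 fold change was -0.60 for lncRNAs and 0.06 for coding genes.

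In the B1 programme list 19 of 21 members rose, 1 fell and 1 did not pass, the same adjusted over the list alone (camera adjusted p = 4.40e-09, adjusted p = 0.163 with an estimated correlation). The repressor gene Zbtb32 (9.46 ± 0.29), the checkpoint receptor gene Ctla4 (6.98 ± 0.44) and Bhlhe41 (5.78 ± 0.20) rose, and Bhlhe40 (-0.78 ± 0.21) fell. Mitosis genes were higher, among them Nek2 (5.01 ± 0.29), Cenpf (3.33 ± 0.42) and Ccna2 (3.19 ± 0.36). In all 26 of 29 members rose, 0 fell and 3 did not pass, the same adjusted over the list alone (camera adjusted p = 1.92e-07, adjusted p = 0.743 with an estimated correlation). For DNA replication 15 of 29 members rose, 2 fell and 12 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0454, adjusted p = 0.819 with an estimated correlation). Ccne1 (2.14 ± 0.21) and Mcm10 (2.87 ± 0.35) rose, and Rfc3 (-0.94 ± 0.11) fell. Glycolysis genes such as Tpi1 (1.92 ± 0.18) and the glucose transporter gene Slc2a1 (1.23 ± 0.09) rose, while Slc2a3 (-0.98 ± 0.20) and Pdk1 (-0.64 ± 0.10) fell. Here 15 of 20 members rose, 3 fell and 2 did not pass, and 17 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.0179, adjusted p = 0.819 with an estimated correlation). With the macrophage gene level in the model neither glycolysis (adjusted p = 0.478) nor DNA replication (adjusted p = 0.753) passed, nor did B cell transcription factors (adjusted p = 0.0580). Of B cell transcription factors, 12 of 22 members fell, 5 rose and 5 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0262, adjusted p = 0.720 with an estimated correlation). Id3 (-3.29 ± 0.18), Irf8 (-2.76 ± 0.11) and Bach2 (-2.73 ± 0.18) fell, and Tcf4 (1.11 ± 0.11) and Irf4 (0.67 ± 0.11) rose. In the MHC class II list 10 of 15 members fell, 2 rose and 3 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0224, adjusted p = 0.771 with an estimated correlation). Icosl (-5.79 ± 0.27) and Ciita (-1.93 ± 0.11) were lower, and the costimulatory genes Cd80 (6.16 ± 0.34) and Cd86 (0.64 ± 0.11) higher. Interferon response genes Oasl1 (-3.19 ± 0.15), Usp18 (-3.15 ± 0.20) and Irf7 (-2.90 ± 0.20) fell, and Ddx58 (0.36 ± 0.12) rose. In all 20 of 26 members fell, 2 rose and 4 did not pass, the same adjusted over the list alone (camera adjusted p = 2.12e-04, adjusted p = 0.731 with an estimated correlation).

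Macrophage genes were higher in the B1a libraries, among them Prg4 (9.20 ± 0.51), Vsig4 (7.71 ± 0.80) and Timd4 (4.97 ± 0.64), and Gata6, a factor of peritoneal macrophages, was 149-fold (95% counting interval 50.5 to 727) higher. In all 12 of 15 members rose, 0 fell and 3 did not pass, the same adjusted over the list alone (camera adjusted p = 0.00104, adjusted p = 0.771 with an estimated correlation). Of neutrophil genes, 8 of 13 members fell, 1 rose and 4 did not pass, and 9 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0262, adjusted p = 0.819 with an estimated correlation). Ngp (-4.88 ± 1.08) and S100a9 (-4.75 ± 1.03) fell and Prtn3 (3.0 ± 1.0) rose (with limma-voom adjusted p = 0.285). All 9 natural killer genes fell (9 adjusted over the list alone, camera adjusted p = 0.00463, adjusted p = 0.765 with an estimated correlation), with Gzma (-4.75 ± 0.77) lowest. Of the fixed lists, 10 of 31 passed, 5 higher and 5 lower; their adjusted p ran from 0.163 to 0.819 with an estimated correlation.

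**Figure D4:**
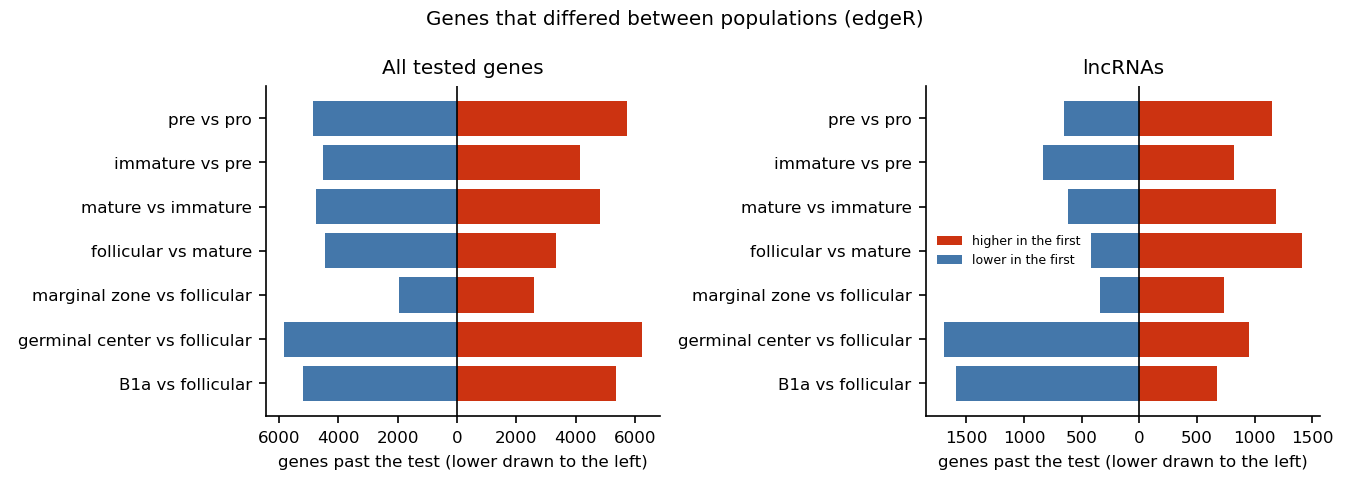
Number of genes with adjusted p below 0.05 in each of 7 comparisons (bars; red higher and blue lower in the population named first) among 17117 tested genes (left) and 3822 lncRNAs (right). LncRNAs that changed were mostly lower in germinal center (1694 of 2643) and B1a cells (1588 of 2259), and mostly higher in follicular than in mature cells (1409 of 1824, but 49.4% of 231 with the granule gene level in the model).

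Genes restricted to 1 population, that is at least 2-fold higher there than in each of the other 7 with every adjusted p below 0.05, numbered 2846, of which 905 were lncRNAs. B1a cells had 752 (163 lncRNAs), pro B cells 637 (158), germinal center cells 588 (265), mature B cells 326 (25), pre B cells 244 (113), marginal zone cells 190 (115), follicular cells 55 (46) and immature B cells 54 (20). In pro B cells Dlx1 exceeded every other population by a log2 fold change of at least 5.03, and in pre B cells Ren1, the renin gene, by 3.87 and Il2ra by 2.92. Wnt10a and Wnt10b marked immature B cells, with smallest log2 fold changes of 4.25 and 3.67. The macrophage genes Siglec1 (3.92) and Fcgr1 (3.62) headed those of mature B cells, where without mature replicate 1 the number restricted was 121 in place of 326. For follicular cells Egr3 (1.16) and Shank1 (1.08) stood first, and without follicular replicate 15 the number was 32 in place of 55. Marginal zone cells were marked by Tsga13 (7.76) and Adam28, germinal center cells by Ackr4, the embryonic globin gene Hbb-bh1 (8.09) and Dlg5 (7.08), and B1a cells by Krt8, Ahnak2 and Prg4, which is also in the macrophage list.

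**Figure D5:**
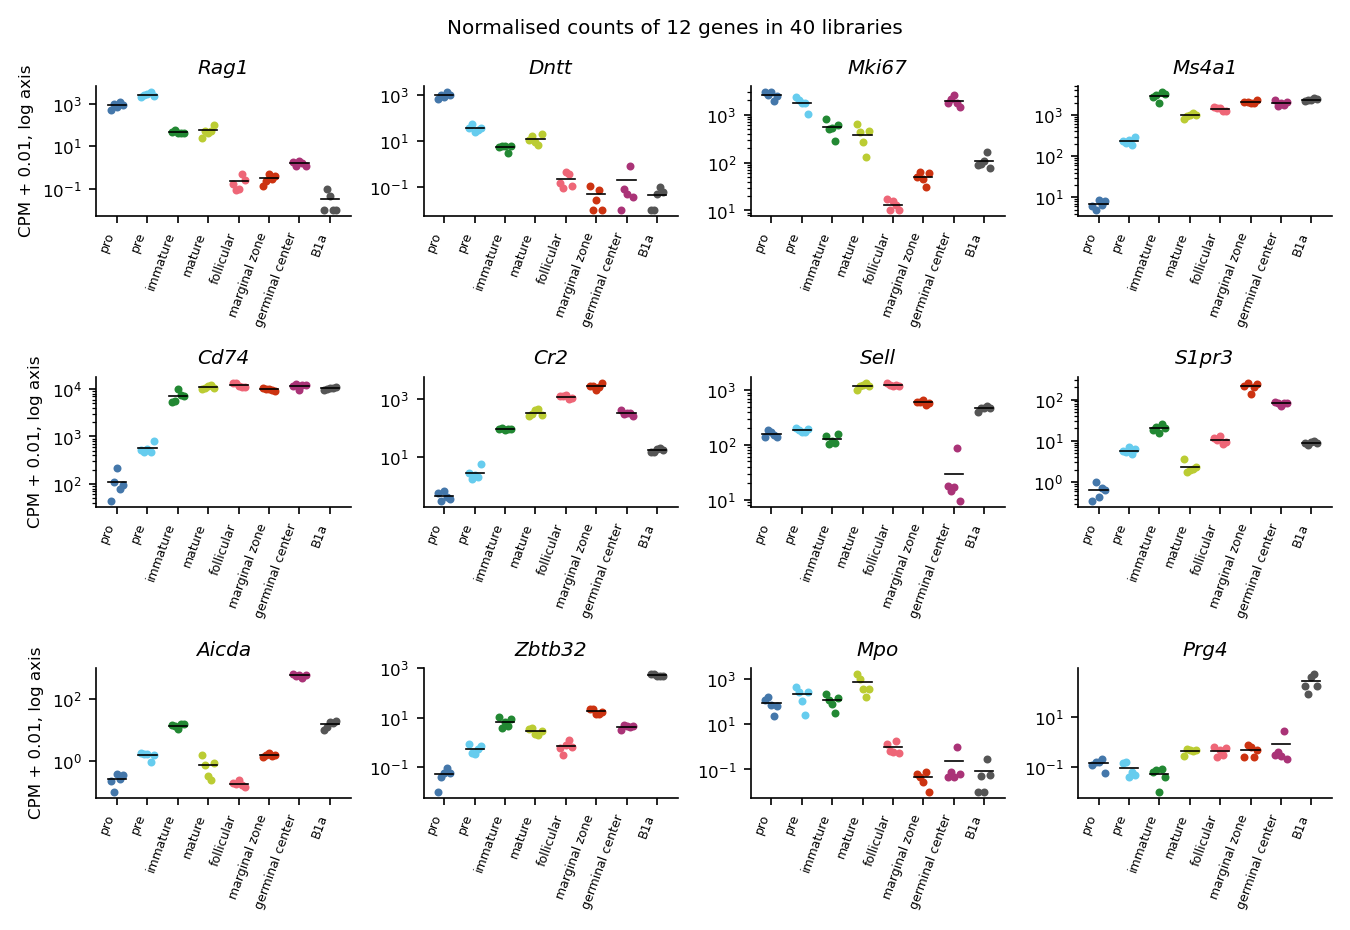
Normalised CPM plus 0.01 (log axis) of 12 genes in the 8 populations; 1 point per library, black lines are means of 5. Rag1 falls from 2079 to 3623 CPM in pre to 41.2 to 58.6 in immature B cells, and Aicda reaches 485 to 662 CPM in germinal center cells.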

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

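Chosen only after the result was seen were the tests on granule genes, on macrophage genes, and on level-matched genes and scaling for lncRNAs.

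For 8 sets of library totals, 24 sets of shares and 535 printed gene levels, the distance of the extreme library from its nearest neighbour was set against the range of its 5 libraries, both in log2, and a ratio above 0.71 was taken as standing apart. By chance about 1 in 20 groups would, and 0 totals, 1 share and 17 gene levels did. Germinal center replicate 14 had the highest share of macrophage genes, 0.0342% against 0.00182% to 0.00358% (ratio 0.769), and its Sell level of 89.0 CPM stood apart from 9.42 to 17.7 (ratio 0.720), so this library differs in more than 1 way. Marginal zone replicate 13 stood apart for Asb2 (34 against 59.3 to 70 CPM, ratio 0.770), LNCGmm02390 (4.46 against 7.87 to 9.48 CPM, ratio 0.753), Ndrg1 (3.62 against 1.52 to 1.79 CPM, ratio 0.815), and Tspan15 (11.2 against 21.4 to 27.6 CPM, ratio 0.718), and no reason for this is given in the labels. Usp18 lay lowest in B1a replicate 1, at 0.859 CPM against 1.32 to 1.48 in the others (ratio 0.796). Ptprc was highest in B1a replicate 2 with 1240 CPM, where the others had 1160 to 1170 (ratio 0.938). LNCGme02460 had its lowest B1a value in replicate 4, 28.3 CPM beside 48.8 to 59.8 (ratio 0.728). LNCGsm09194 lay lowest in follicular replicate 11, at 1.42 CPM against 2.89 to 3.6 in the others (ratio 0.763). Pfkm was highest in follicular replicate 14 with 5.05 CPM, where the others had 3.03 to 3.47 (ratio 0.738). Cdt1 had its highest immature value in replicate 3, 129 CPM beside 72.1 to 85.3 (ratio 0.713). Fyn lay highest in immature replicate 3, at 52.7 CPM against 42.3 to 43.1 in the others (ratio 0.911). Trpm5 was highest in immature replicate 3 with 27.8 CPM, where the others had 20 to 21.5 (ratio 0.778). Igll1 had its lowest immature value in replicate 4, 1.87 CPM beside 4.01 to 4.71 (ratio 0.824). Smtnl2 lay lowest in pre replicate 1, at 48 CPM against 62.4 to 66.3 in the others (ratio 0.810). Aicda was lowest in pre replicate 4 with 0.936 CPM, where the others had 1.58 to 1.84 (ratio 0.776). Itga4 had its lowest pre value in replicate 5, 339 CPM beside 457 to 486 (ratio 0.834).

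Granule genes in the marrow libraries move together. Within populations, each of the 13 neutrophil genes followed the mean of the others over the 20 bone marrow libraries. The median slope was 0.981 (0.888 to 1.13), as in any set that moves together. Their share differed 7.29-fold between the highest and lowest mature library, where the B cell receptor list differed 1.4-fold, which argues against expression set by the stage of the sorted cells. The 29 mitosis genes followed this level in the mature libraries with a median slope of 0.757 (0.647 to 0.832 leaving out each library), and 323 genes restricted to mature B cells followed the macrophage level there with 0.866 (0.747 to 0.969), so part of the mitosis signal and most of that restricted set may come from other marrow cells. A slope of at least 0.5 was found for 28 of 29 mitosis genes and 87.9% of the restricted genes, against 11.7% and 7.87% of the other tested genes. Which cells gave this RNA, and whether some mature B cells divide, was not tested.

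In the 5 B1a libraries the 15 macrophage genes followed each other with a median slope of 1.05 (0.658 to 1.36), which leaves their source open. Their share differed 6.96-fold between the highest and lowest B1a library, where the B cell receptor list differed 1.08-fold, which argues against a level set by the B1a cell type. For 747 genes restricted to B1a cells the median slope on the macrophage level was -0.00158 (-0.0150 to 0.0158), so macrophage RNA does not account for that set as a whole, although 10.8% of its genes had a slope of at least 0.5, against 5.28% of other tested genes. The tissue of origin stays open as an explanation for the set and was not tested.

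LncRNAs were lower as a class in germinal center and B1a cells. Low abundance argues the other way, as coding genes of the same level had a median log2 fold change of 0.148 in germinal center (0.00003 to 0.222 over 10000 sets) and 0.263 in B1a cells (0.137 to 0.387). A library scaling moves all genes alike, and the lncRNA median minus the coding median was -0.581 and -0.653. With libraries thinned to the smallest total, lncRNA medians were -0.482 and -0.550, which argues against depth. Candidates are lower lncRNA abundance in these cells, a high follicular level (lncRNA median 0.465 against mature cells) and a catalogue built from unequal material. None was tested directly.

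Other splits of the same libraries test whether a count could arise by chance. In 100 splits of the 10 libraries of each comparison, the real split gave 10286 genes for pre with pro against at most 0 for any other, 6466 against 2 for immature with pre, 6847 against 680 for mature with immature, 7000 against 2197 for follicular with mature, 6093 against 0 for marginal zone, 10956 against 0 for germinal center and 10118 against 0 for B1a. For lncRNAs the values were 1417 against 0, 1000 against 0, 1088 against 54, 1303 against 382, 1071 against 0, 1979 against 0 and 1638 against 0. In each case 1 split of 100, the real one, gave so many. Chance is excluded only where libraries exchange freely. Same-numbered marrow libraries may not (r up to 0.54). Pro and pre libraries were taken as paired, and only 16 splits part all 5 pairs, too few for a share below 0.05. The real split gave 10286 genes and 1417 lncRNAs, or 10980 and 1497 with the block, against 0 and 0 for the other 15. Over 40 regroupings of all libraries, the real one gave 16988 genes that differ between populations against 164. It gave 2846 restricted genes and 905 restricted lncRNAs against 0 and 0 (1 of 40, under the same condition).

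For the number of lists past camera chance cannot be excluded. In the order above the real split gave 12, 13, 14, 13, 10, 8 and 9 lists against at most 19, 16, 18, 15, 15, 19 and 13 for other splits, and 34, 30, 9, 26, 19, 71 and 40 of 100 splits gave as many. How much a list past this test says by itself stays open. Member counts rest on single-gene calls, made for 4550 to 12047 of 17117 genes.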

How the results depend on the processing

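The covariates for neutrophil and macrophage genes, the tau without mature libraries, the list tests in only 10 libraries and the exchange of shares within pairs were chosen after seeing the data; the other alternatives were set before. Among values of all 568 pairs of gene and comparison that the naming rule gives, 97.1% kept their call and sign when single libraries were left out and 96.7% under the other alternatives. For the 339 printed it was 99.9% and 98.9%, and for the 229 not printed 93.0% and 93.5%; printed genes were picked in part for stability. For lists it was 96.0% and 75.9%. Of pairs not printed, 41 values turned sign, 31 of them under the other alternatives, and 3 of these passed with the opposite sign: Lyz2 (2.65, adjusted p = 0.00257, -5.06 in the model without covariate) and Fcgr1 (3.88, adjusted p = 0.00580, -3.90) in follicular with mature cells under the neutrophil covariate, and Id2 (-1.01, adjusted p = 9.71e-04, 0.922) in B1a cells under the macrophage covariate.

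With the neutrophil covariate 1690 genes and 231 lncRNAs differed between follicular and mature cells in place of 7788 and 1824, and with the macrophage covariate 5166 and 1208. As the covariate tracks tissue, a call it ends need not be due to other cells. Under the neutrophil covariate the signs of 3 printed genes turned without passing, Pfkm (log2 fold change 0.083, -1.26 without it), Epor (1.65) and Pf4 (1.22); under the macrophage covariate Nkg7 (-0.456) and Gzma (-0.048) in mature B cells and Prtn3 (-1.39) in B1a cells turned. Of lists for follicular with mature, B cell receptor signalling turned lower (adjusted p = 0.0415, signed -log10 of it -1.38) and the macrophage list higher (adjusted p = 3.78e-07, signed -log10 6.42), while mitosis, DNA replication and early B progenitor lists passed under both covariates. The erythroid, mast cell and platelet lists did not pass with the neutrophil covariate (adjusted p from 0.133 to 0.841), and glycolysis passed under neither. B cell receptor signalling did not pass with the macrophage covariate (0.0829). Elsewhere the neutrophil and macrophage covariates ended the call of dendritic (0.0933 and 0.655) and natural killer genes (0.298 and 0.982) in mature B cells and of erythroid genes in marginal zone cells (0.409 and 0.0568), besides the lists named in the report. The neutrophil covariate alone ended that of natural killer genes in B1a cells (0.102), and the macrophage covariate alone that of homing (0.0552) and mast cell genes (0.0506) in mature B cells and of the 3 lists named in the report in B1a cells. A list whose own mean is the covariate loses its change by construction and is left out here. With limma-voom Cenpf in marginal zone cells did not pass (0.0514), nor the 3 genes named in the report.

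A filter of 1 CPM in 5 libraries left 1204 changed lncRNAs for mature with immature (1812 in the model of all genes), 1624 for germinal center (2643) and 1466 for B1a cells (2259). With only the 10 libraries of a comparison, 1000 lncRNAs changed for immature with pre (1662) and 1088 for mature with immature (1812). This ended 8 list calls: besides B cell receptor signalling in mature and homing in germinal center cells, B cell transcription factors in pre (adjusted p = 0.0688) and B1a cells (0.0866), germinal center, immediate early and marginal zone genes (0.0534) in immature, and DNA replication in B1a cells (0.0589). Upper-quartile scaling moved the median change in germinal center cells by -0.16 and the 1 CPM filter by -0.11, and the latter moved that of follicular with mature cells by 0.11.

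With an estimated correlation 3 of 217 list tests passed in place of 75: survival genes in immature B cells, the marginal zone list in marginal zone cells and the germinal center list in germinal center cells (by comparison 0, 1, 0, 0, 1, 1 and 0). Fry, which asks a different question, gave 142 in all, with 25 for pre with pro, 21 for immature with pre, 23 for mature with immature, 19 for follicular with mature, 20 for germinal center and 24 for B1a cells.

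At a fold of at least 4 the restricted genes (lncRNAs in parentheses) were 1177 (440) in all: 278 (93) in pro, 67 (42) in pre, 13 (5) in immature, 68 (2) in mature, 0 (0) in follicular, 81 (49) in marginal zone, 296 (152) in germinal center and 374 (97) in B1a cells. At 0.5 CPM 572 lncRNAs were detected in all populations in place of 364.

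Leaving out single libraries moved the restricted genes of mature B cells, 326, to between 121 (without mature replicate 1) and 450 (without mature replicate 4), and the lncRNAs among them from 25 to 11 without mature replicate 1, 41 without mature replicate 4 and 39 without pre replicate 5. Those of follicular cells went from 55 to between 32 (without follicular replicate 15) and 78 (without follicular replicate 11), and the lncRNAs from 46 to 25 without follicular replicate 15 and 70 without follicular replicate 11. The difference in lncRNA share between follicular and mature cells, 0.754 points, ranged from 0.611 to 0.893. The macrophage share of mature over immature cells did not pass without any 1 immature library (0.0909 to 0.125). Without follicular replicate 12, 13, 14 or 15 the differences of neutrophil and macrophage shares between follicular and mature cells and of the macrophage share between B1a and follicular cells had an adjusted p of 0.05. Of printed genes, Slc16a3 in pre B cells did not pass without pre replicate 1 (adjusted p = 0.0614), nor Cdt1 in immature B cells without pre replicate 3 (0.0751), pre replicate 4 (0.0850) or immature replicate 3 (0.186). Among lists, mitosis in pre B cells did not pass without pro replicate 1 or 3 or pre replicate 4 or 5 (adjusted p from 0.0550 to 0.0737), plasma cell genes in pre B cells without pro replicate 2, 3 or 4 or pre replicate 1 (0.0512 to 0.0613), B cell receptor signalling in mature B cells without immature replicate 3 or 4 or mature replicate 1, 2 or 5, and DNA replication in B1a cells without B1a replicate 2 or 4 or follicular replicate 14 or 15 (0.0635 to 0.103). Macrophage genes in follicular with mature cells did not pass without mature replicate 1 or 2 or follicular replicate 12. Another 6 lists lost their call without 1 or 2 libraries, with adjusted p from 0.0512 to 0.0642. Called genes ranged from 6468 (without mature replicate 1) to 8047 for follicular with mature cells and from 11763 to 12473 (without germinal center replicate 14) for germinal center cells.

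With the replicate block, 10545 genes differed between pre and pro B cells. Of lists with a call, only plasma cell genes lost it, as did the lncRNA share (0.575 points). Lists and shares without a call were not run. In the other comparisons that share numbers the pairing was not seen in all pairs. For immature with pre and mature with immature, numbers 1, 4 and 5 correlated best with their own (0.34 to 0.54). Numbers 2 and 3 did not (0.00052 to 0.12). Same numbers gave -0.13 to 0.063 for marginal zone and -0.3 to 0.063 for germinal center with follicular cells. The block gave 8797, 9189, 4423 and 11527 genes there. With it V(D)J recombination (adjusted p = 0.0509) and immediate early genes (0.0536) in immature, B cell receptor signalling in mature (0.0609) and homing genes in germinal center cells (0.0582) did not pass. No paired analysis was possible because B1a and follicular cells, and follicular and mature cells, share no replicate numbers.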

Other observations

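No test in this part was chosen before the results were seen, and it describes single genes only.

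Aicda lay between 11.1 and 15.9 CPM in the 5 immature B cell libraries, against 0.936 to 1.84 in pre and 0.230 to 1.58 in mature B cells, and 485 to 662 in germinal center cells. S1pr3, a sphingosine phosphate receptor gene, lay between 15.3 and 25.7 CPM in immature B cells, between 1.71 and 3.58 in mature B cells and at 137 or more in marginal zone cells.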
